A study of Mus musculus with 11 samples.

How the data were processed

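Gene expression was measured by RNA sequencing of oligo(dT)-selected mRNA in 11 libraries of WFU3, a line of mouse prostate epithelial stem cells. The cells carried lentiviral short hairpin RNAs (shRNAs) against Map3k7, against Chd1, against both, or control hairpins only. The labels describe random-hexamer cDNA synthesis and give no strand marking, no sequencing batch and no statement that the libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples.

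The deposited raw table holds expected counts, that is, estimated read counts per gene that are not normalized, 1 column per library. Per the labels, the authors used Bowtie2 and RSEM 1.3.1 on the mouse genome GRCm38, and they also name limma; the annotation and the strand setting of the counting are not given in the sources used here. The deposited normalized table holds log2 values: log2 of (count + 0.5) on a per-million scale of an effective library size, as limma voom gives them. For 17963 genes found in both tables, each library's normalized values departed from log2 of (raw count + 0.5) by 1 constant, to within 5.02e-09 on the log2 scale. The raw table lists 48299 genes by symbol, of which 23412 had 0 in all libraries. The normalized table lists 17966, with a smallest row total of 11.01 counts, and the largest total left out of it was 11. Dates stood in place of 25 symbols of the raw counts, 16 of them among the genes tested; these genes were kept in the fits and cannot be named. Between 7.83% and 9.11% of the cells of a library were not whole numbers. Every column of values belonged to a sample.

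Counts were rounded to whole numbers and analysed in R 4.3.3. Total counts ran from 14132371 to 23163709 per library. The most abundant gene, Fn1, took 1.06% to 1.97% of a library and the 10 most abundant genes 5.78% to 7.07%. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14346 genes and removed at most 0.117% of a library's counts. Of these, 14175 matched a gene of GENCODE M21 by symbol, which gave coordinates on GRCm38, counted from 1. A count of 3 in a library corresponded to 0.130 to 0.212 counts-per-million (CPM). Where a group had 0 counts of a gene, the fold is given as a lower bound computed from 3 counts over the whole group, and with 1 to 3 counts in a group the ratio of the pooled counts is given with its 95% counting interval. Reads carried no molecular identifiers, so these intervals and bounds cover counting error only. RSEM divides reads shared between similar genes, so values of close paralogs (Krt6a and Krt6b) and of ribosomal protein genes depend on that division.

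Differences were tested with edgeR 4.0.16: normalization factors by the trimmed mean of M-values (TMM), a model with a mean for each of the 4 groups over all 11 libraries, the quasi-likelihood F-test, and Benjamini-Hochberg adjustment over the 14346 genes. A gene was called at an adjusted p under 0.05 with no fold threshold. The comparisons were shMap3k7, shChd1 and shDouble against shControl, shDouble against shMap3k7, shDouble against shChd1, and the interaction of both knockdowns, that is, shDouble less shMap3k7 less the difference of shChd1 and shControl. Libraries of a line (a clone) are related by design: both shChd1 lines derive from control clone 4, and the shDouble lines derive from the shMap3k7 clones. The difference between clone 1 and clone 7 correlated across genes with r = 0.500 between the shMap3k7 libraries and the shDouble libraries. A fit with the line as a replicate block was therefore run wherever the groups share lines, and its values are given beside the results for shChd1 and for the interaction. CPM values are TMM-scaled, given as mean ± SD with the number of libraries, and log2 fold changes are given ± SE.

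The genes to be named were set by a rule: Map3k7 and Chd1 throughout; in each comparison with shControl the 8 largest rises and the 8 largest falls, and in the others 4 each way, among called genes with a mean of at least 5 CPM in the higher group and log2 CPM ranges of the 2 groups that do not overlap (the interaction is exempt from this last part). Predicted genes were passed over, and where no gene passed, the 4 with the smallest p are given. Genes so named were thus higher, or lower, in every library of their group than in any of the other. Some genes that the rule picks are not reported here. Of each called gene list up to 4 members with the smallest adjusted p could be named, and of other lists up to 2 past the threshold. The rule, the gene lists, the comparisons and most alternatives were fixed before the data were examined.

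The 24 gene lists were androgen response, prostate luminal markers, prostate basal markers, epithelial junction and identity, mesenchymal and EMT (epithelial to mesenchymal transition), TGF-beta response, NF-kB targets, JNK and AP-1 early response, TAK1 pathway members, CHD family, interferon response, cell cycle S and G2/M, homologous recombination and DNA damage repair, p53 targets, cholesterol and fatty acid synthesis, hypoxia and glycolysis, unfolded protein response, ribosomal proteins, stem and progenitor markers, and markers of neuroendocrine cells, fibroblasts, smooth muscle, immune cells and endothelium. Each was tested by camera of limma 3.58.1 on voom values with the preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated from the data was run beside it. With the estimated correlation no list was called in any comparison. Some genes stand in more than 1 list, namely 10 of the 40 measured mesenchymal genes, 11 of 56 androgen response, 7 of 16 luminal, 6 of 23 stem, 6 of 34 cholesterol, 5 of 31 JNK and AP-1, 4 of 30 TGF-beta, 4 of 35 p53, 4 of 8 fibroblast, 3 of 39 epithelial, 3 of 23 basal, 3 of 45 NF-kB and 3 of 37 hypoxia genes. At most 2 did in each of the others. The TAK1 pathway list holds Map3k7 and the CHD family list holds Chd1, so the counts of these lists include the targeted genes.

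Principal components were computed on the log2 CPM (prior count 0.5) of the 500 most variable genes. Comparisons that share the control libraries are correlated even without any effect, so the correlation of log2 fold changes across genes was set against 20 simulated data sets with unchanged groups. The 3 control libraries were not divided between comparisons, since 1 part would hold a lone library. The tests were tried on simulated counts with known changes. These were drawn independently for each gene and library, without line effects, so the false calls do not give the error rate in these data. Of 100 genes changed 4-fold, the edgeR test recovered 81 in shMap3k7, 83 in shChd1 and 92 in shDouble against shControl, 84 in shDouble against shMap3k7, 90 in shDouble against shChd1 and 69 for the interaction, with 2 to 11 false calls. Of 100 genes changed 2-fold it recovered 55, 44, 64, 51, 57 and 21. The DESeq2 Wald test made 29 to 40 false calls on the same simulated counts. With the line block, 70 of 100 genes changed 4-fold were recovered in shChd1 against shControl, 80 in shDouble against shMap3k7 and 58 for the interaction. Of 100 genes changed 2-fold, the fit with the line block recovered 12, 48 and 2. A list raised in the simulated counts was called and none of the other 23 lists was. Without correlation between genes in the simulation, this does not show how often unchanged lists are called in these data. The alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma-voom, no low-count filter, a filter of 1 CPM in at least 4 libraries, a fold threshold of 1 on the log2 scale, only the groups compared, the line as a replicate block, a correlation between libraries of a line (estimated at 0.631), counts summed per line, the deposited normalized table, and leaving out each library in turn. A fit with each chromosome centred per library was added after seeing the data. Isoforms and sequence variants were not analysed here.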

Results

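The libraries fell into 4 groups that cross knockdown of Map3k7, which encodes the kinase TAK1, with knockdown of Chd1, which encodes a chromatin-remodelling ATPase. The shControl group held 3 libraries: an unnumbered control line at passage 30 (replicate 1) and control clones 4 and 5 at passage 52 (replicates 2 and 3). The labels number control lines 4 and 5 but use the word clone only for the Map3k7 lines. Calling these control lines clones is a reading of their numbers. By the labels, the hairpins of replicate 1 were marked puro and neo, and those of all other libraries GFP and puro. The shMap3k7 group held 2 libraries, clone 1 at passage 49 and clone 7 at passage 47. The shChd1 group held 2 libraries, made with hairpin constructs 96526 (passage 52) and 96528 (passage 50), both in control clone 4. The shDouble group held 4 libraries, both constructs in each of Map3k7 clones 1 (passage 49) and 7 (passage 48). Total counts were 15298380, 18859722 and 18238437 in shControl and 15925142 and 14132371 in shMap3k7. They were 15520540 and 14846114 in shChd1, and 23163709, 22329280, 19937320 and 17277242 in shDouble. The stated purpose of the series was to identify genes differing between these 4 groups.

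Map3k7 mRNA was lower in every library of a Map3k7 clone, to about 31.0% of control. Map3k7 (ENSMUSG00000028284.13, chromosome 4, 31964097 to 32023467) measured 124, 137 and 140 CPM in shControl (134 ± 8.91, n = 3). It measured 43.0 and 40.1 CPM in shMap3k7 (41.5 ± 2.07, n = 2) and 41.7, 40.9, 42.2 and 39.3 CPM in shDouble (41.0 ± 1.27, n = 4). In shChd1 it was 138 and 138 CPM (138 ± 0.264, n = 2). The log2 fold change against shControl was -1.69 ± 0.10 in shMap3k7 (adjusted p = 2.9e-05) and -1.71 ± 0.07 in shDouble (adjusted p = 2.2e-06).

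Chd1 mRNA was reduced far less. Chd1 (ENSMUSG00000023852.14, chromosome 17, 15704967 to 15772610) measured 212, 195 and 204 CPM in shControl (204 ± 8.61, n = 3), 221 and 238 CPM in shMap3k7 (229 ± 12.4, n = 2), 145 and 150 CPM in shChd1 (148 ± 3.43, n = 2) and 198, 162, 194 and 190 CPM in shDouble (186 ± 16.3, n = 4). The shChd1 mean was 72.6% of control, and the shDouble mean was 91.3% of control and 81.1% of shMap3k7. Set against the library of the same line without a Chd1 hairpin, Chd1 stood at 74.6% and 77.1% in clone 4, 89.7% and 73.5% in clone 1, and 81.5% and 79.7% in clone 7. In shChd1 it fell by 0.46 ± 0.10 on the log2 scale (adjusted p = 0.047). With the line as a replicate block it was -0.40 (adjusted p = 0.134). Over the alternatives the adjusted p ran from 8.3e-04 with the DESeq2 Wald test to 0.4999 with counts summed per line. The call ended without each of the libraries in turn except shControl replicate 2, with adjusted p = 0.0546 (without shDouble replicate 2) to 0.413 (without shChd1 replicate 2). In shDouble, Chd1 changed by -0.13 ± 0.09 against shControl (adjusted p = 0.291) and by -0.30 ± 0.10 against shMap3k7 (adjusted p = 1), neither past the threshold.

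**Figure D1:**
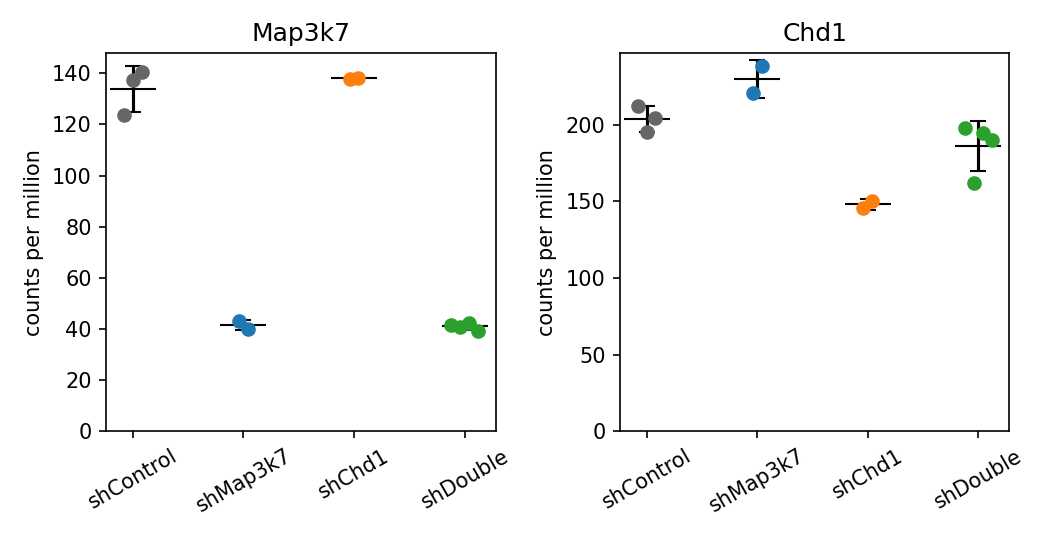
Map3k7 and Chd1 in CPM (vertical axes) in each of the 11 libraries (points) by group, with group means and SD. Map3k7 lay between 39.3 and 43.0 CPM in the 6 libraries of Map3k7 clones and at 124 CPM or more in the others, while Chd1 lay between 145 and 238 CPM throughout.

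Across the 500 most variable genes, the first principal component held 71.8% of the variance and separated the 6 libraries of Map3k7 clones, with scores of 38.3 to 52.6, from the 5 others. Control scores were -41.8, -63.6 and -17.7 for replicates 1, 2 and 3, and the shChd1 libraries lay beyond them at -76.9 and -76.2. The second component, with 7.5%, separated clone 1 from clone 7. Both shChd1 libraries correlated across genes with the clone 4 control at r of at least 0.973 and with the other controls at r of at most 0.935. Libraries of the same Map3k7 clone correlated at r of at least 0.977, and libraries of different Map3k7 clones at r of at most 0.969, with or without a Chd1 hairpin. The 3 control libraries correlated with each other at r of at least 0.952.

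**Figure D2:**
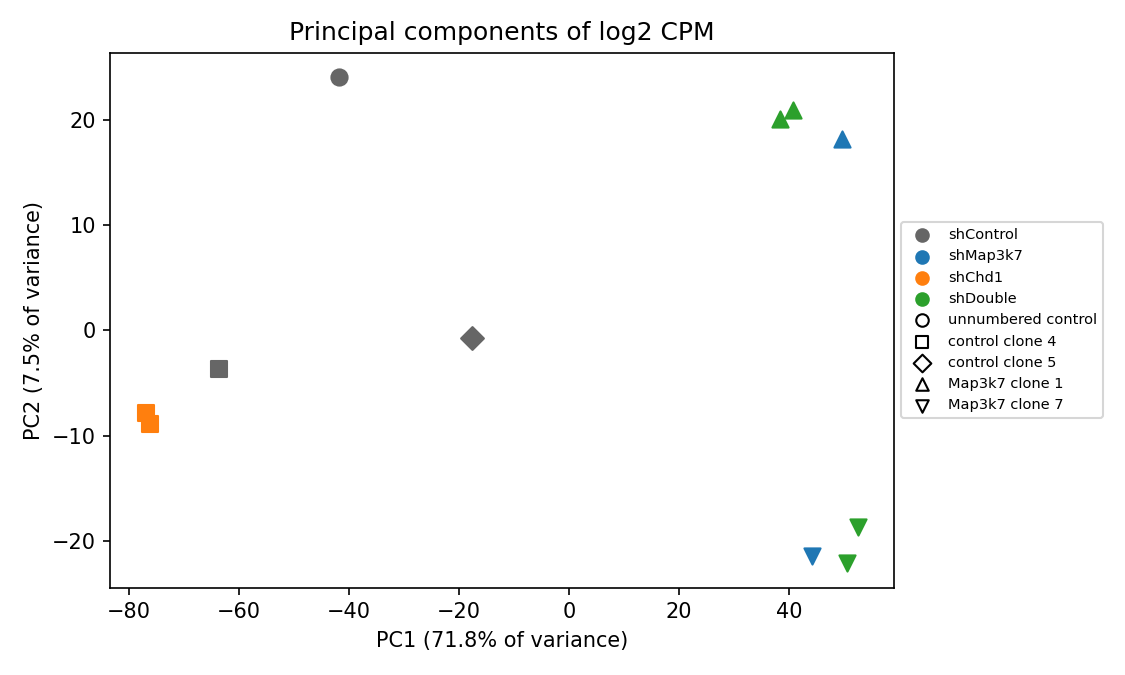
Scores of the 11 libraries (points, coloured by group) on the first and second principal components of the 500 most variable genes, in log2 CPM units. The first axis (71.8% of the variance) separates the 6 libraries of Map3k7 clones from the shControl and shChd1 libraries, and the second (7.5%) separates clone 1 from clone 7.

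Map3k7 knockdown was compared with shControl. The Map3k7 clones held far less of several cytokine and collagen transcripts. Il6, an inflammatory cytokine, fell by 5.58 ± 0.59 on the log2 scale, from 16.8 ± 6.22 CPM (SD, n = 3) to 0.351 ± 0.221 (SD, n = 2; adjusted p = 8.5e-04). Col5a1, a fibrillar collagen chain, fell from 125 ± 38.1 to 0.536 ± 0.574 CPM (adjusted p = 6.6e-04), and Zeb1, a transcription factor that represses epithelial genes, from 31.7 ± 16.0 to 0.460 ± 0.374 CPM (adjusted p = 0.00253). Jag1, a Notch ligand, rose from 109 ± 11.9 to 379 ± 72.8 CPM (log2 1.80 ± 0.17, adjusted p = 4.8e-04). In all, 1712 of 14346 genes were called, 697 higher and 1015 lower. The test pooled the spread over all groups, and shChd1 and shDouble hold libraries of the same line. Within a line, libraries of these groups correlated at r of 0.981 to 0.987, against 0.952 to 0.957 among the control lines. The adjusted p thus rests in part on spread within lines, here and in the other comparisons. With only the groups compared far fewer genes were called, as given under processing below. Of these, 805 changed at least 2-fold, 170 higher and 635 lower.

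The largest rises were Dgkk, a diacylglycerol kinase, from 2.48 ± 2.87 to 89.4 ± 71.9 CPM (log2 5.16 ± 1.02), and Arfgef3, from 1.14 ± 0.0931 to 31.7 ± 0.713 CPM (log2 4.78 ± 0.14, adjusted p = 8.1e-08). Slain1, a microtubule-binding protein, rose by 4.70 ± 0.89, the mechanosensitive channel gene Piezo2 by 4.5 ± 1.29, and Col4a4, a basement membrane collagen chain, by 4.26 ± 0.39 on the log2 scale. The muscarinic receptor gene Chrm3 rose by 4.03 ± 0.72, the bradykinin receptor gene Bdkrb2 by 3.81 ± 0.61 and Cntfr, a subunit of the ciliary neurotrophic factor receptor, by 3.68 ± 0.79. The shMap3k7 clones differed widely in some of these genes. In shMap3k7, Piezo2 stood at 12.7 ± 15.1 CPM (SD, n = 2), Slain1 at 7.03 ± 6.15 and Chrm3 at 10.9 ± 9.44. Among the falls, 4 genes had no count in either shMap3k7 library. Scarf2, from 17.2 ± 5.12 CPM, was at least 168-fold lower, Rspo3, a potentiator of Wnt signalling, from 12.7 ± 4.71 CPM, at least 126-fold lower, the proton pump gene Atp12a at least 99.5-fold lower and Tspan11 at least 90.2-fold lower. Fbln1, an extracellular matrix glycoprotein, had 1 count against 1808, a ratio of 987 (counting interval 177 to 38989). Bgn, a matrix proteoglycan, had 1 against 1244, a ratio of 679 (122 to 26833), and the calcium channel gene Cacna1g 2 against 1970, a ratio of 537 (149 to 4441). The controls varied widely in these genes, at 32.5 ± 38.5 CPM for Fbln1, 24.6 ± 25.3 for Bgn and 35.4 ± 32.0 for Cacna1g. The pooled ratios therefore do not hold alike for each control. Dpysl3, a cytoskeletal regulator, fell from 94.1 ± 52.9 to 0.138 ± 0.0105 CPM (log2 -9.35 ± 0.87, adjusted p = 4.6e-04).

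Most NF-kB target genes were lower. Of 45 measured NF-kB targets 0 rose and 20 fell over all genes tested, and 1 rose and 26 fell adjusted over the list alone (median log2 -1.10, camera adjusted p = 1.1e-07; adjusted p = 0.479 with an estimated correlation). Besides Il6 they included Cxcl2, a neutrophil chemokine (log2 -5.62 ± 0.67), Bcl3, an NF-kB cofactor, from 45.8 ± 12.1 to 7.39 ± 3.37 CPM, and Saa3, an acute-phase protein, with 3 counts against 808, a ratio of 147 (50.1 to 714). Interferon response genes were lower: of 40 measured 0 rose and 9 fell, and 1 rose and 14 fell adjusted over the list alone (median -0.97, camera adjusted p = 4.7e-04; adjusted p = 0.532 with an estimated correlation). Isg20 fell by 1.66 ± 0.20, Herc6 fell by 1.13 ± 0.27 and Gbp7 fell by 2.76 ± 0.69 on the log2 scale, and Zbp1, a nucleic acid sensor, had 2 counts against 219, a ratio of 59.8 (16.3 to 496). Hypoxia and glycolysis genes were lower, with 1 of 37 measured up and 7 down, and 1 up and 14 down adjusted over the list alone (median -0.45, camera adjusted p = 0.00113; adjusted p = 0.532 with an estimated correlation). Lox, which crosslinks collagen, fell from 266 ± 107 to 5.60 ± 4.23 CPM, Pfkfb3 fell by 1.77 ± 0.37 and P4ha1, a collagen prolyl hydroxylase, fell by 0.99 ± 0.22, while Mxi1 rose by 0.79 ± 0.18. The hypoxia and glycolysis median against the control mean was -0.47, 0.35 and 0.13 in shControl replicates 1, 2 and 3. It was -0.47 and -0.33 in the shMap3k7 libraries, so shControl replicate 1 was not apart from them.

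Of 40 mesenchymal and EMT genes 2 rose and 18 fell, and 3 rose and 25 fell adjusted over the list alone (median -1.67, camera adjusted p = 1.8e-05; adjusted p = 0.532 with an estimated correlation). The collagen genes Col6a1 and Col6a2 fell by 5.84 ± 0.78 and fell by 7.49 ± 1.23 on the log2 scale. Of 8 measured fibroblast markers 0 rose and 4 fell, and 6 fell adjusted over the list alone (median -2.70, camera adjusted p = 0.00986; adjusted p = 0.532 with an estimated correlation). Pdgfrb, a fibroblast and pericyte receptor, had 1 count against 794, a ratio of 433 (77.5 to 17134), Col3a1 1 against 914, a ratio of 499 (89.3 to 19721), and Twist2 fell by 3.14 ± 0.67. Against the control mean the fibroblast median stood at 0.86, 0.32 and -0.96 in shControl replicates 1, 2 and 3, and between -3.11 and -2.0 in the 6 libraries of Map3k7 clones. Epithelial junction and identity genes were higher, with 7 of 39 measured up and 2 down, and the same counts adjusted over the list alone (median 0.46, camera adjusted p = 7.7e-05; adjusted p = 0.532 with an estimated correlation). Desmosomal Dsg2 rose by 0.72 ± 0.13, whereas tight-junction Tjp1 fell by 0.52 ± 0.10 and Ehf, an epithelial transcription factor, fell from 178 ± 86.6 to 18.2 ± 8.56 CPM.

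Luminal markers were called up by camera (adjusted p = 0.00938; adjusted p = 0.532 with an estimated correlation) with 0 of 16 measured past the edgeR test over all genes, and 5 up and 1 down adjusted over the list alone. Their median was 0.66 and their mean -0.11; Krt18 measured 1382 ± 655 and 2993 ± 94.7 CPM (adjusted p = 0.052). Ribosomal proteins were shifted upwards, 6 up and 0 down of 75, 5 and 0 adjusted over the list alone (median 0.18, camera adjusted p = 4.9e-07), with Rps29 at 0.60. Cholesterol and fatty acid synthesis genes gave 4 and 0 of 34, 8 and 0 adjusted over the list alone (median 0.26, camera adjusted p = 0.00131), with Hmgcs1 at 0.54 and Fdft1 at 0.61. Cell cycle S and G2/M genes gave 4 and 1 of 52, also adjusted over the list alone (median 0.15, camera adjusted p = 0.00131). The replication nuclease gene Fen1 rose by 0.81 ± 0.09 and the mitotic kinase gene Aurkb fell by 1.09 ± 0.12. Of p53 targets 3 rose and 2 fell of 35, and the same adjusted over the list alone (median 0.25, camera adjusted p = 0.0136), with Plk2 at 0.91 and Pmaip1, an apoptosis inducer, at 1.84. Of unfolded protein response genes 5 rose and 1 fell of 29, with 6 and 2 adjusted over the list alone (median 0.10, camera adjusted p = 0.0148), with Atf4 at 0.80 and Asns at 1.09. For these 5 lists adjusted p = 0.532 with an estimated correlation. Some list medians against the control mean overlapped or lay close. P53 targets stood at 0.115 in shControl replicate 1 and 0.102 in shMap3k7 replicate 2. Unfolded protein response genes stood at 0.172 in shControl replicate 3 and 0.119 in shMap3k7 replicate 2, and luminal markers at 0.550 and 0.584.

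Camera called none of the other 12 lists. Counts up and down of measured genes are given for them, then those adjusted over the list alone. They were androgen response (6 and 7 of 56; 11 and 9; median 0.06 but mean -0.17), basal markers (2 and 2 of 23; 3 and 2; median 0.09 but mean -0.29), TGF-beta response (2 and 4 of 30; 4 and 8), JNK and AP-1 early response (1 and 1 of 31, also alone; median 0.09 but mean -0.01). They were also TAK1 pathway members (2 and 2 of 25, also alone; median 0.02 but mean and test downward), CHD family (0 and 1 of 10; 0 and 0), and homologous recombination and DNA damage repair (1 and 0 of 42; 0 and 0). Stem and progenitor markers gave 3 and 3 of 23 (3 and 4; median 0.01 but mean -0.70), neuroendocrine markers 0 and 0 of 7 (0 and 2), smooth muscle markers 0 and 1 of 4 (0 and 1), immune cell markers 0 and 1 of 4 (1 and 1; median 0.54 but test downward) and endothelial markers 0 and 1 of 5 (0 and 2). Their camera adjusted p ran from 0.162 to 0.911. Named members past the test were Steap4 (log2 -6.21), Abcc4 (1.42), Thbs1 (1.49), Cd14 (-2.80) and Mylk (-3.66).

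The count of 1712 was 1073 without shControl replicate 2, 261 without shMap3k7 replicate 1 and 520 without shMap3k7 replicate 2. Without shMap3k7 replicate 1, 8 of the 16 genes with the largest changes and 22 of 60 list members stayed called. Without shMap3k7 replicate 2, 13 and 27 did, and without any other library at least 14 and 53. The p53 call was lost without shControl replicate 2 (median 0.13) or shMap3k7 replicate 1 (0.09), and the unfolded protein call without shControl replicate 1 (0.13) or shMap3k7 replicate 1 (0.10). Basal markers were called up without shControl replicate 1 (0.46), and DNA repair genes without shControl replicate 2 (0.17) or shMap3k7 replicate 1 (0.16). Without shControl replicate 2 the medians were 0.42 for luminal markers, 0.19 for epithelial genes, -0.60 for interferon genes, 0.24 for the cell cycle and 0.17 for the unfolded protein response. The cell cycle median was 0.10 without shControl replicate 1 and 0.23 without shMap3k7 replicate 1, and the unfolded protein median was 0.24 without shMap3k7 replicate 2.

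Genes of chromosome 19 were higher as a group in the Map3k7 clones. Of 468 tested genes there, 32.5% were called higher in shMap3k7 against 3.87% of genes elsewhere, and 41.7% against 9.14% in shDouble. The median log2 departure of chromosome 19 genes from the control mean was 0.51 to 0.54 in the 3 clone 1 libraries and 0.34 to 0.36 in the 3 clone 7 libraries, against -0.04 to 0.03 in the controls. Fen1 and Mxi1, which rose, and Fas, which fell, lie on this chromosome. Chromosome 4 stood at 0.34 in clone 1 and 0.13 in clone 7, chromosome 7 at -0.34 in clone 7 and chromosome 8 at 0.27 in clone 7. Control lines were shifted too, by less. The clone 4 control stood at -0.14, -0.15 and -0.16 on chromosomes 5, 10 and 16, and the shChd1 libraries at -0.21 to -0.26 on 5 and 10. On chromosome 14 shControl replicate 1 stood at 0.18, against -0.07 and -0.11 in replicates 2 and 3. In shChd1 against shControl, 1 gene of chromosome 10 was called higher and 34 lower.

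**Figure D3:**
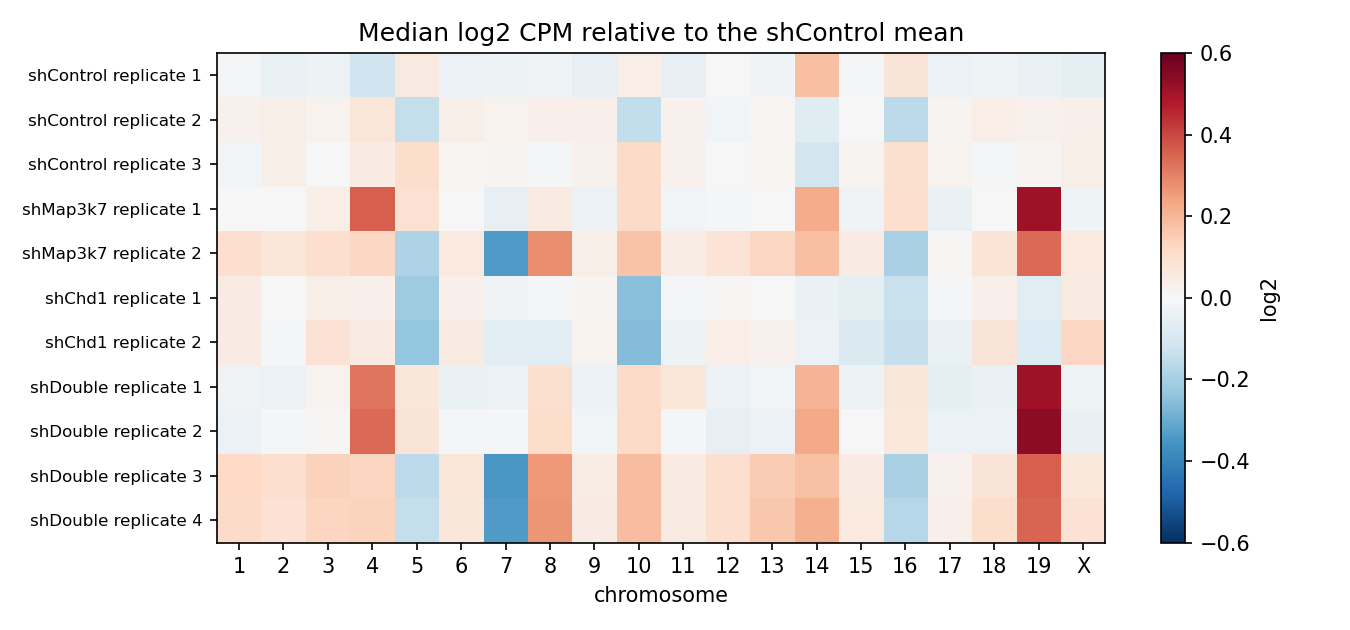
Median log2 departure from the control mean of the genes of each chromosome (horizontal axis), for each library (vertical axis), shown by colour. Chromosome 19 stands at 0.34 or more in all 6 libraries of Map3k7 clones, and chromosome 7 at about -0.34 in the 3 clone 7 libraries.

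Chd1 knockdown was compared with shControl. The shChd1 libraries held less of several epithelial transcripts and more of several interferon-response transcripts, and the clone 4 control from which they derive stood apart from the other controls in the same directions. Krt8, a luminal keratin, fell from 2285 ± 885 CPM (SD, n = 3) to 819 ± 48.5 (SD, n = 2; log2 -1.48 ± 0.27, adjusted p = 0.0324). Dsp, a desmosomal linker protein, fell from 563 ± 203 to 184 ± 17.0 CPM (adjusted p = 0.0253). Bst2, an interferon-induced antiviral protein, rose from 11.04 ± 3.31 to 25.6 ± 4.46 CPM (log2 1.21 ± 0.23, adjusted p = 0.0354). The edgeR test called 417 genes, 95 higher and 322 lower, and 207 of these changed at least 2-fold.

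The largest rise was Atp12a, from 10.3 ± 2.07 to 77.9 ± 8.93 CPM (log2 2.91 ± 0.23, adjusted p = 0.00404), the gene that had no count in shMap3k7. The noradrenaline transporter gene Slc6a2 rose by 2.63 ± 0.50, the membrane peptidase gene Mme from 15.6 ± 8.35 to 94.7 ± 21.7 CPM, and Fibin by 2.31 ± 0.54. The transcription factor gene Tfcp2l1 rose by 2.20 ± 0.35, the interferon-inducible gene Mndal by 2.07 ± 0.43, the fucosyltransferase gene Fut9 by 2.04 ± 0.38 and the glycolytic gene Aldoc by 1.97 ± 0.42. Wnt7a, a secreted signalling protein, fell by 6.58 ± 1.16. The keratin genes Krt6a and Krt6b fell by 6.46 ± 1.41 and fell by 6.10 ± 1.42, Krt6a from 576 ± 800 CPM, a mean with an SD above it. The chemokine gene Ccl2 fell by 4.68 ± 1.04, Fam81a fell by 4.67 ± 0.95 and the cytokine gene Il24 fell from 18.3 ± 8.72 to 0.783 ± 0.213 CPM. Foxj1, the regulator of motile cilia, fell from 122 ± 89.9 to 7.46 ± 7.15 CPM, and Dynap fell by 3.90 ± 0.67.

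Of 39 epithelial junction and identity genes 0 rose and 18 fell, and 1 rose and 33 fell adjusted over the list alone (median -1.21, camera adjusted p = 9.2e-15; adjusted p = 0.482 with an estimated correlation). Pkp1 fell by 1.19 ± 0.17, the adhesion molecule gene Epcam fell by 1.17 ± 0.21 and the epithelial splicing regulator gene Esrp1 fell by 1.24 ± 0.23. Of 23 basal markers 0 rose and 9 fell, 12 adjusted over the list alone (median -0.90, camera adjusted p = 8.7e-06; adjusted p = 0.482 with an estimated correlation), among them Lama3 (log2 -2.61), Lamb3 (-0.81) and S100a14 (-3.36). Of 16 luminal markers 0 rose and 4 fell, 7 adjusted over the list alone (median -1.14, camera adjusted p = 0.0137; adjusted p = 0.734 with an estimated correlation), with Krt18 at -1.66 and Cldn7 at -1.41. Of 31 JNK and AP-1 early response genes 0 rose and 6 fell, 13 adjusted over the list alone (median -0.63, camera adjusted p = 2.7e-06; adjusted p = 0.482 with an estimated correlation), with Fosb at -3.05, Klf4 at -1.02 and Myc at -1.04. Interferon response genes were higher, 4 of 40 up and 0 down, 12 up and 0 down adjusted over the list alone (median 1.14, camera adjusted p = 1.5e-14; adjusted p = 0.482 with an estimated correlation), with the viral RNA sensor gene Ddx58 at 0.69, B2m at 0.68 and Parp9 at 1.07. The clone 4 control, without a Chd1 hairpin, had a median of -0.63 for epithelial, -0.69 for luminal and 0.62 for interferon genes against the control mean. The other controls had 0.22 and 0.33, 0.18 and 0.55, and -0.41 and -0.21, and the shChd1 libraries -1.02 and -1.27, -1.04 and -1.09, and 1.39 and 1.14. Hypoxia and glycolysis genes were higher, 2 up and 0 down of 37, also adjusted over the list alone (median 0.40, camera adjusted p = 3.0e-05), with Aldoc and Ero1l (0.79). For this list the clone 4 control had a median of 0.35 against the control mean, near the 0.52 and 0.45 of the shChd1 libraries. The other controls had -0.47 and 0.13.

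Cell cycle genes were called down, 0 up and 3 down of 52, also adjusted over the list alone (median -0.15, camera adjusted p = 0.00296; adjusted p = 0.787 with an estimated correlation), with the mitotic kinase gene Plk1 at -0.64. The cell cycle median against the control mean was -0.12 in shControl replicate 1 and -0.03 in shChd1 replicate 2, so the groups overlapped. P53 targets were called down by camera with 0 of 35 past the edgeR test, also adjusted over the list alone (median -0.33, camera adjusted p = 0.00324). Their median against the control mean was -0.22 in the clone 4 control and -0.24 and -0.39 in the shChd1 libraries. For p53 targets and for hypoxia and glycolysis adjusted p = 0.734 with an estimated correlation. Camera called none of the other 16 lists, with adjusted p from 0.0664 to 0.948. Counts up and down, then adjusted over the list alone, were 0 and 4 of 56 for androgen response (1 and 7) and 0 and 0 of 40 for mesenchymal and EMT genes (0 and 0; median -0.01 but test upward). They were 0 and 0 of 30 for TGF-beta response (3 and 10), 1 and 4 of 45 for NF-kB targets (1 and 6; mean -0.34 but test upward), 0 and 1 of 25 for TAK1 pathway members (also alone), 1 and 1 of 10 for the CHD family (2 and 1) and 0 and 0 of 42 for DNA repair (also alone). They were 1 and 0 of 34 for cholesterol and fatty acid synthesis (3 and 2), 0 and 1 of 29 for the unfolded protein response (also alone), 0 and 1 of 75 for ribosomal proteins (0 and 0), 2 and 6 of 23 for stem and progenitor markers (4 and 8) and 0 and 0 of 7 for neuroendocrine markers (also alone). Fibroblast markers gave 0 and 0 of 8, smooth muscle markers 0 and 1 of 4, immune cell markers 0 and 0 of 4 (median 0.14 but mean -0.58) and endothelial markers 0 and 0 of 5 (median -0.03 but test upward), each also alone. In the stem and progenitor list Jag1 fell by 1.34 ± 0.18 and Notch1 rose by 0.77 ± 0.13.

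All shChd1 libraries derive from control clone 4, and this comparison depended on the line and on most libraries. With the line as a replicate block 142 genes were called, 50 higher and 92 lower, 94 of them shared with the 417, and limma-voom called 515 with 283 higher and 232 lower. Of the 16 genes with the largest changes 9 stayed past the threshold with the block, among them Atp12a (log2 3.07), Mme (1.95), Krt6a (-3.19) and Il24 (-3.38). So did 18 of 37 list members, among them Dsp (-0.84), Krt8 (-0.69), Epcam (-0.66) and Jag1 (-1.39). The block moved the log2 change by over 1.5 times in 11 of the 16 genes and in 23 of the 37 members. Calls were lost for Wnt7a (-4.21), Krt6b (-3.21), Ccl2 (-2.67), Fam81a (-1.94), Foxj1 (-1.29), Fibin (1.61) and Mndal (1.25). No interferon gene was called with the block, with Bst2 at 0.79, Parp9 at 0.59, B2m at 0.45 and Ddx58 at 0.44. Among other members, Krt18 (-0.53), Cldn7 (-0.60), Klf4 (-0.89) and Myc (-0.66) were lost as well. List medians with the block were -0.51 for epithelial, -0.49 for basal, -0.25 for JNK and AP-1, 0.48 for interferon, 0.13 for hypoxia and -0.22 for cell cycle genes. The block ended the calls for luminal markers (-0.51) and p53 targets (-0.11). The count was 5, 2641 and 4 without shControl replicates 1, 2 and 3, and 68 and 67 without shMap3k7 replicates 1 and 2. It was 4 and 0 without shChd1 replicates 1 and 2, and 30, 68, 72 and 52 without shDouble replicates 1 to 4. Of the 16 genes, all 16 stayed called without shControl replicate 2, but 1 without each other control (Atp12a), 5 and 4 without shMap3k7 replicates 1 and 2, 0 without either shChd1 replicate and 2 to 4 without a shDouble replicate. Of the 37 list members, 37 stayed called without shControl replicate 2 and at most 14 (without shDouble replicate 2) otherwise. The cell cycle call was lost without shControl replicate 2 (-0.09) or shChd1 replicate 1 (-0.04), and its median was -0.24 without shChd1 replicate 2. Without shControl replicate 1 the medians were -0.59 for basal markers and 0.21 for hypoxia genes, and fibroblast markers were called up (0.98), as they were without shChd1 replicate 2 (0.73).

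The shDouble libraries, which carry hairpins against both genes, were compared with shControl; Map3k7 was lower in them, while the change of Chd1 did not pass the test. The shDouble libraries showed the low inflammatory and mesenchymal transcripts seen in the Map3k7 clones from which they derive. Il6 fell from 16.8 ± 6.22 CPM (SD, n = 3) to 0.142 ± 0.101 (SD, n = 4; log2 -6.76 ± 0.47, adjusted p = 2.8e-05), Col5a1 from 125 ± 38.1 to 0.801 ± 0.862 CPM (adjusted p = 3.8e-05) and Trp63, the basal transcription factor p63, from 9.56 ± 3.82 to 1.27 ± 0.796 CPM (adjusted p = 0.00279). Tmprss2, a luminal serine protease, rose from 6.26 ± 5.31 to 27.5 ± 3.52 CPM (adjusted p = 0.025). The test called 3413 genes, 1467 higher and 1946 lower, of which 1307 changed at least 2-fold, 260 higher and 1047 lower. The 4 shDouble libraries come from 2 clones. With limma-voom and a correlation within lines the count was 1557, and with counts summed per line 590.

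The largest rises were Dgkk (log2 4.83 ± 0.96), Arfgef3 (4.78 ± 0.13, adjusted p = 4.4e-08), Slain1 (4.71 ± 0.83), Col4a4 (4.23 ± 0.36), Chrm3 (4.14 ± 0.67), Bdkrb2 (3.95 ± 0.57), Shox2 (3.69 ± 0.32) and Cntfr (3.53 ± 0.73). Shox2, a homeobox gene, went from 3.46 ± 1.31 to 44.5 ± 12.1 CPM (adjusted p = 8.8e-05). The largest falls were in genes with 1 to 3 counts over the 4 shDouble libraries. The steroid-metabolising gene Akr1c18 had a ratio of 672 (counting interval 185 to 5554), Scarf2 of 696 (192 to 5753), Pdgfrb of 597 (165 to 4939) and the collagen gene Col5a2 of 633 (113 to 25069). Col3a1 had a ratio of 458 (156 to 2226), Adgrg2 of 479 (132 to 3964) and Atp12a of 411 (113 to 3405). Dpysl3 fell by 8.28 ± 0.55 on the log2 scale.

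Of 45 NF-kB targets 1 rose and 26 fell, 1 and 30 adjusted over the list alone (median -1.16, camera adjusted p = 4.2e-08; adjusted p = 0.448 with an estimated correlation), with Cxcl2 at -6.91, Bcl3 at -3.02 and Saa3 at -8.08. Of 40 mesenchymal and EMT genes 3 rose and 27 fell, also adjusted over the list alone (median -1.59, camera adjusted p = 7.8e-06), and Zeb1 fell by 6.11 ± 0.59. Of 40 interferon response genes 0 rose and 20 fell, 1 and 24 adjusted over the list alone (median -1.05, camera adjusted p = 1.5e-05), with Isg20 at -1.67 and Gbp2 at -2.76. Of 37 hypoxia and glycolysis genes 1 rose and 17 fell, 2 and 19 adjusted over the list alone (median -0.47, camera adjusted p = 1.1e-04), with Lox at -5.24 and the oxygen-sensing hydroxylase gene Egln3 at -4.31. Of 8 fibroblast markers 0 rose and 6 fell, 7 adjusted over the list alone (median -2.89, camera adjusted p = 0.00139), and Pdgfra fell by 1.23 ± 0.18. Cholesterol and fatty acid synthesis genes were higher, 13 up and 0 down of 34, 20 and 3 adjusted over the list alone (median 0.37, camera adjusted p = 1.8e-05), with Acaca at 0.56, Hmgcs1 at 0.57 and Fasn at 0.38. Ribosomal protein genes were higher, 13 and 0 of 75, 12 and 0 adjusted over the list alone (median 0.18, camera adjusted p = 7.8e-06), as were cell cycle genes, 9 and 1 of 52, 7 and 1 adjusted over the list alone (median 0.19, camera adjusted p = 1.1e-04). Luminal markers gave 5 up and 1 down of 16, 6 and 2 adjusted over the list alone (median 0.71, camera adjusted p = 0.00725). Krt18 rose by 1.06 ± 0.29 and the pioneer factor gene Foxa1 by 0.87 ± 0.24, and Psca had 1 count against 41, a ratio of 61.7 (10.5 to 2494). For these lists adjusted p = 0.602 with an estimated correlation. Against the control mean the luminal median was 0.55 in shControl replicate 3 and 0.49 and 0.41 in shDouble replicates 3 and 4. The hypoxia and glycolysis median was -0.47 in shControl replicate 1, within the shDouble range of -0.53 to -0.38. Epithelial junction and identity genes gave 9 up and 3 down of 39, 11 and 4 adjusted over the list alone (median 0.49, camera adjusted p = 8.4e-05; adjusted p = 0.612 with an estimated correlation), and Ehf fell by 3.57 ± 0.36.

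Camera called none of the other 14 lists, with adjusted p from 0.0560 to 0.834. Counts up and down, then adjusted over the list alone, were 12 and 10 of 56 for androgen response (15 and 11; median 0.12 but mean -0.14) and 3 and 6 of 23 for basal markers (7 and 7; median 0.23 but mean -0.23). They were 3 and 8 of 30 for TGF-beta response (6 and 9), 4 and 1 of 31 for JNK and AP-1 early response (also alone), 5 and 3 of 25 for TAK1 pathway members (also alone; median -0.01 but test upward), 2 and 1 of 10 for the CHD family (3 and 1; median -0.03 but test upward) and 3 and 1 of 42 for DNA repair (1 and 0). They were 3 and 2 of 35 for p53 targets (also alone), 3 and 2 of 29 for the unfolded protein response (also alone), 4 and 6 of 23 for stem and progenitor markers (5 and 8; median 0.10 but mean -0.58), 1 and 3 of 7 for neuroendocrine markers (also alone), 0 and 1 of 4 for smooth muscle markers (1 and 2), 1 and 1 of 4 for immune cell markers (2 and 1; median 0.69 but test downward) and 0 and 2 of 5 for endothelial markers (also alone). Among members past the test, Jag1 rose by 1.85 ± 0.15, the monocyte receptor gene Cd14 fell by 3.0 ± 0.20, Csf1r rose by 2.57 ± 0.75 and Fas, a death receptor gene, fell by 2.81 ± 0.48.

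The count was 2181 without shControl replicate 2, and the 16 genes with the largest changes stayed called with each of the 11 libraries left out, as did 59 to 65 of 66 list members. The 4 shDouble libraries come from 2 clones, so leaving out 1 of them keeps both clones and does not test dependence on a clone. Without shControl replicate 2 the medians were 0.45 for luminal and 0.23 for epithelial genes, and without shControl replicate 1 the cell cycle median was 0.12. P53 targets were called up (median 0.22 to 0.27) without shControl replicate 1 or 3, shMap3k7 replicate 1 or 2, or shDouble replicate 3 or 4; basal markers without shControl replicate 1 (0.48); and DNA repair genes without shControl replicate 2 or shDouble replicate 2 (both 0.16).

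**Figure D4:**
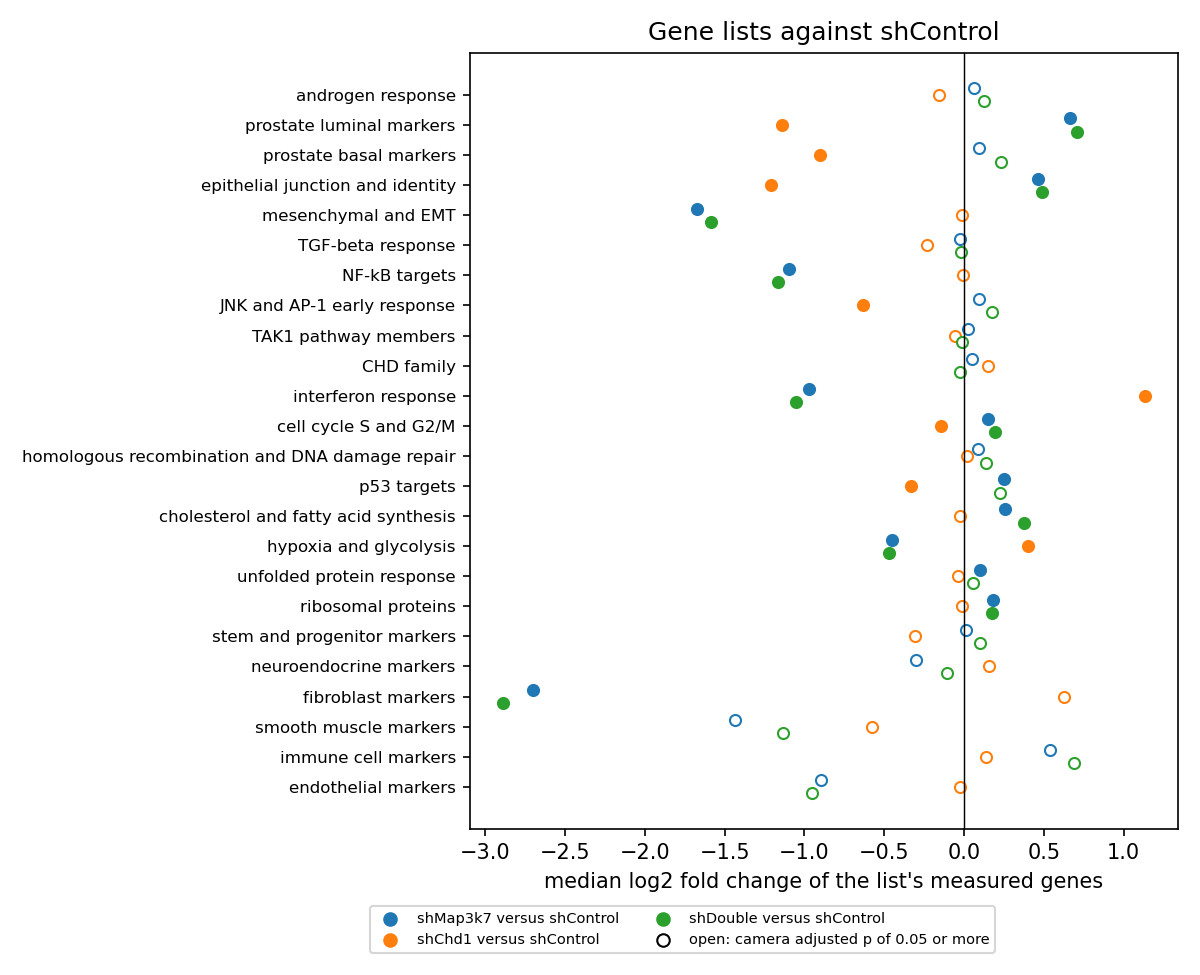
Median log2 fold change against shControl (horizontal axis) of the measured genes of the 24 lists (vertical axis) in shMap3k7, shChd1 and shDouble. Filled points were called by camera with its preset correlation; interferon genes stand at -0.97 in shMap3k7, 1.14 in shChd1 and -1.05 in shDouble.

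The effect of Chd1 hairpins within the Map3k7 clones was read from shDouble against shMap3k7. The edgeR test called 0 of 14346 genes, with 115 at an unadjusted p under 0.05, and the DESeq2 Wald test, limma-voom and every other alternative, the line block and each left-out library included, also called 0. The 4 genes with the smallest p were Gm12928, at 0 in shMap3k7 and at least 11.7-fold higher at 1.20 ± 0.289 CPM in shDouble (n = 4), Gm45902 (log2 0.63), Rsc1a1 (0.84) and Gm13534 (2.08), each with adjusted p = 1. Camera called cholesterol and fatty acid synthesis genes up with 0 of 34 past the edgeR test, also adjusted over the list alone (median 0.08, camera adjusted p = 2.5e-04). It called unfolded protein response genes down with 0 of 29 past it, also adjusted over the list alone (median -0.11, camera adjusted p = 4.6e-05). For both, adjusted p = 0.901 with an estimated correlation. Acaca, the first enzyme of fatty acid synthesis, differed by 0.17, and the endoplasmic reticulum chaperone genes Calr and Hspa5 by -0.23 and -0.19. Of the other 22 lists none was called and none had a member past the test, over all genes or adjusted over the list alone, with camera adjusted p from 0.124 to 0.810. Both list calls were lost without shMap3k7 replicate 1 (0.08 and -0.08). With the line as a replicate block NF-kB targets (-0.09), interferon response (-0.12), p53 targets (-0.06) and ribosomal proteins (-0.02) were called down as well. Other lists were called when a library was left out: p53 targets without shMap3k7 replicate 2 (-0.21) or shDouble replicate 1 (-0.10), DNA repair without shMap3k7 replicate 2 (0.10), the cell cycle without shDouble replicate 1 (0.07) or 2 (0.06), interferon genes without shControl replicate 2 (-0.12) or shDouble replicate 2 (-0.11), and NF-kB targets (-0.13) and ribosomal proteins (-0.05) without shDouble replicate 3.

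Map3k7 knockdown in the presence of Chd1 hairpins was read from shDouble against shChd1, which also differ in clone. Epithelial genes were higher and interferon, mesenchymal and inflammatory genes lower in shDouble. Part of this may come from clone 4. The clone 4 control, without a Chd1 hairpin, had medians of -0.63 for epithelial, -0.69 for luminal and 0.62 for interferon genes against the control mean. In shDouble these were 0.53 to 0.78, 0.41 to 0.92 and -1.20 to -0.77. Jag1 rose from 43.0 ± 10.6 CPM (SD, n = 2) to 392 ± 36.4 (SD, n = 4; log2 3.19 ± 0.19, adjusted p = 1.0e-05). Ehf fell from 540 ± 35.8 to 14.96 ± 5.17 CPM, and Nid1, a basement membrane protein, from 272 ± 20.97 to 0.143 ± 0.115 CPM (adjusted p = 0.00118). The test called 6426 genes, 3241 higher and 3185 lower, 2861 of them at least 2-fold. It took libraries of the same line as independent, and the lower counts that allow for lines are given under processing below.

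Mtap, an enzyme of methionine salvage, had 12477 counts against 1, a ratio of 4946 (counting interval 888 to 195386), and the cell cycle inhibitor gene Cdkn2b, nearby on chromosome 4, was at least 267-fold higher; both were near 0 in the clone 4 control as well, with Mtap at 0.259 CPM against 96.8 and 110 CPM in the other controls. The fitted log2 change of Mtap was reversed, at -1.67, with limma-voom and a correlation within lines. Trim44 was at least 172-fold and Zfp518b at least 142-fold higher. Zfp518b too was at 0 CPM in every clone 4 library, the control included, against 8.19 CPM or more in all other libraries. Atp12a had a ratio of 3134 (867 to 25894) and Col3a1 of 2389 (817 to 11590) in the lower direction, and the coagulation factor gene F5 was at least 349.8-fold lower. Of the lists, 13 were called. Epithelial junction and identity (34 up and 3 down of 39; 35 and 3 adjusted over the list alone; median 1.77, camera adjusted p = 3.5e-10), luminal markers (10 and 1 of 16, also alone; 2.02, adjusted p = 0.00245), basal markers (14 and 4 of 23, also alone; 1.15, adjusted p = 0.00218) and JNK and AP-1 early response (16 and 3 of 31; 16 and 4 alone; 0.57, adjusted p = 0.00140) were higher. Cell cycle (24 and 1 of 52, also alone; 0.33, adjusted p = 1.5e-05), p53 targets (16 and 4 of 35; 17 and 4 alone; 0.54, adjusted p = 0.00208), cholesterol synthesis (20 and 3 of 34; 21 and 3 alone; 0.45, adjusted p = 0.00179) and ribosomal proteins (25 and 1 of 75; 18 and 1 alone; 0.15, adjusted p = 0.00101) were higher as well. Interferon response (0 and 33 of 40; 0 and 34 adjusted over the list alone; median -2.02, adjusted p = 3.3e-11), hypoxia and glycolysis (2 and 25 of 37; 2 and 26 alone; -0.94, adjusted p = 4.4e-06), NF-kB targets (6 and 26 of 45; 7 and 27 alone; -0.87, adjusted p = 3.4e-04), mesenchymal and EMT genes (2 and 21 of 40; 4 and 23 alone; -1.54, adjusted p = 5.8e-04) and fibroblast markers (0 and 7 of 8, also alone; -4.27, adjusted p = 0.00276) were lower. Adjusted p = 0.495 with an estimated correlation for cholesterol synthesis and 0.442 for the other 12. Esrp1 (2.22), Krt8 (2.21), Fosb (4.67) and Fasn (0.74) rose, and Bst2 (-2.34), Parp9 (-2.04), P4ha1 (-1.83) and Nod2 (-3.96) fell. The 11 lists not called had camera adjusted p from 0.201 to 0.901. The count was 4273 and 3683 without shChd1 replicates 1 and 2. Of the 8 genes with the largest changes 6 and 5 stayed called without these, and 7 without shDouble replicate 1 or 2.

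The interaction compared the difference of shDouble from shMap3k7 with that of shChd1 from shControl. The shControl mean covers 3 lines, so the interaction also holds the difference of clone 4 from the other controls; with the line as a replicate block the comparison was made within clones. The edgeR test called 0 of 14346 genes, with 1998 at an unadjusted p under 0.05 and a smallest adjusted p of 0.144, while the DESeq2 Wald test called 395. On simulated counts 39 of 158 DESeq2 calls for the interaction were false, against 6 of 96 with edgeR. The simulation held no line effects, so it cannot decide between the counts of 395 and 0 in these data. The genes with the smallest p included the laminin chain Lama3 (log2 2.71 ± 0.42) and Ahcyl2 (-1.05 ± 0.15), with adjusted p = 0.144; Gm12928 was near 0 in shMap3k7 and shChd1. With the line as a replicate block 11 genes were called, with adjusted p from 0.0428 to 0.0495. Of these, Lama3 (2.19), Cdh3 (2.0), Lypd3 (1.89), Fam83g (1.13), Dsp (0.88) and Krt8 (0.69) had positive values, that is, a more positive change with the Chd1 hairpins in Map3k7 clones than in clone 4. Sema3d (-2.20), Sorbs2 (-1.43), Heg1 (-1.16) and Mt1 (-0.96) had negative ones. The count was 1002 without shControl replicate 2, 1 without shChd1 replicate 1 and 31 without a low-count filter.

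By camera 7 lists differed, each with 0 members past the test over all genes. Positive interactions were found for epithelial junction and identity (28 up and 1 down of 39 adjusted over the list alone; median 1.22, camera adjusted p = 7.8e-15; 0.48 with the line block), basal markers (9 and 0 of 23 alone; 0.94, adjusted p = 9.2e-07; 0.42 with the block), JNK and AP-1 early response (9 and 0 of 31 alone; 0.72, adjusted p = 7.7e-07; 0.38), luminal markers (5 and 0 of 16 alone; 1.33, adjusted p = 0.0082; 0.44) and cell cycle (0 and 0 of 52 alone; 0.16, adjusted p = 0.0016; 0.24). Negative ones were found for interferon response (0 and 5 of 40 alone; -1.10, adjusted p = 1.3e-11; -0.56) and hypoxia and glycolysis (0 and 0 of 37 alone; -0.49, adjusted p = 1.0e-05; -0.18). Adjusted p = 0.482 with an estimated correlation for the epithelial, basal, JNK and AP-1 and interferon lists and 0.672 for the other 3. Ribosomal proteins (-0.06) were called with the block. The other 17 lists had camera adjusted p from 0.0559 to 0.881. The cell cycle call was lost without shControl replicate 2 (0.10) or shChd1 replicate 1 (0.06). Its median was 0.10 without shControl replicate 3, 0.09 without shMap3k7 replicate 1, 0.24 without shMap3k7 replicate 2, 0.25 without shChd1 replicate 2 and 0.11 without shDouble replicate 4, and the hypoxia median was -0.26 without shControl replicate 1. P53 targets were called (0.27 to 0.41) without shControl replicate 2, shMap3k7 replicate 1, shChd1 replicate 1 or shDouble replicate 3 or 4. Without shControl replicate 1 cholesterol synthesis (0.19) and fibroblast markers (-0.93) were called, and without shMap3k7 replicate 1 the CHD family (-0.20).

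The comparisons with shControl were set against each other. The shMap3k7 and shDouble comparisons shared 672 genes called higher and 992 called lower, where 71.3 and 138 would fall together by chance, and 0 went opposite ways. Their log2 fold changes correlated across genes at r = 0.923 (covariance 1.19) against a simulated mean of 0.0377 (covariance 0.00377) for unchanged groups that share controls; these groups also share clones. The shMap3k7 and shChd1 comparisons had 79 genes called in opposite directions (22.4 by chance), 4 both higher (4.62) and 6 both lower (22.8). Their r was -0.250 (covariance -0.248) against a simulated 0.0633 (0.0194 to 0.0974; covariance 0.00986). The shChd1 and shDouble comparisons had 153 genes called in opposite directions (45.8 by chance), 7 both higher (9.71) and 12 both lower (43.7), with r = -0.260 (covariance -0.240) against a simulated 0.0293 (covariance 0.00287). Genes are not independent replicates, the controls were not divided between the comparisons, and the simulated groups did not share lines, as shChd1 and shControl replicate 2 share clone 4. Genes called in the same direction in shMap3k7 and shDouble numbered 253 without shMap3k7 replicate 1, 514 without shMap3k7 replicate 2 and 1049 without shControl replicate 2. Without shControl replicate 2, r was -0.124 for shMap3k7 and shChd1 and -0.113 for shChd1 and shDouble. Genes called in the same direction then numbered 70 for shMap3k7 and shChd1 and 121 for shChd1 and shDouble; without any other library they numbered at most 3 and 5.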

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

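The test of GC content and length and that of the knockdown itself for chromosome 19, and both tests on Mtap, were chosen only after the result was seen; the other tests below were planned, but chromosome medians and the counts with the line block were known when they were written.

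Chromosome 19 genes were higher in all 6 libraries of Map3k7 clones. GC content and transcript length did not account for it. After regression on both, chromosome 19 genes stood 0.4093 above the other chromosomes in shDouble against shControl (log2; bootstrap interval 0.371 to 0.443; 0.396 before the regression); this test at first took the residual against 0 and was changed because skewed folds left the other chromosomes at 0.187. An extra copy of the chromosome in the clones is a candidate explanation: every 10 Mb stretch with at least 20 genes was shifted, the lowest by 0.3339 and the highest by 0.547, and the last stretch, with 9 genes, by 0.29. The Map3k7 knockdown itself cannot be told apart from it, because the lowest chromosome 19 median over the 6 libraries was 0.3402 and no Map3k7 hairpin library lies outside these 2 clones.

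Mtap (chromosome 4, 89137122 to 89181081) and Cdkn2b (89306299 to 89311039) were near 0 in all 3 clone 4 libraries, and Cdkn2a, which lies between them, had no count there against 3.81 and 0.935 CPM in the other controls. The Chd1 hairpins are excluded as the cause for Mtap, because the clone 4 control, which carries none, held 0.2514% of the Mtap level of the other controls. Whether clone 4 has lost this locus cannot be told apart from silencing: the longest run of adjacent genes lost in clone 4 was 2 (3 had been asked for), since Cdkn2a lay under the minimum level of the test. In all, 9 genes were lost in the clone 4 libraries by the same rule, among them Gm12606, between Mtap and Cdkn2b, and Gpx2, Galk1, Ptprb, Zfp518b and Cpa4 on other chromosomes. Low levels of Galk1, Ptprb and Cpa4 were not particular to clone 4. Their lowest values in the other libraries were 0.0521, 0.119 and 0.715 CPM. Gm12602, Mtap, Gm12606, Cdkn2a and Cdkn2b, 5 neighbours in a row, were at most at 0.259 CPM in each clone 4 library, as loss of the locus would give, though most were low in the other controls too.

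Chd1 hairpins came with 417 called genes against the controls and 0 within the Map3k7 clones. Part of the 417 may reflect clone 4 rather than Chd1: 96.16% of these genes (401 of 417) differed between the clone 4 control and the other controls in the same direction as shChd1, against 75.84% of all genes. A response of the same kind but smaller in the Map3k7 clones was not seen, as 48.59% (69 of 142) of the genes called within clone 4 had the same sign there, and their median absolute log2 change was 1.12 in clone 4 and 0.108 in the Map3k7 clones. The fit within clone 4 rests on 1 control library, so a difference of that library alone stays open. Chd1 itself measured 74.6% and 77.1% of the 1 library without a Chd1 hairpin in clone 4 and between 73.5% and 89.7% in the Map3k7 clones, with adjusted p = 0.134 with the line block and 1 in shDouble against shMap3k7.

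Of the 35 splits of the shDouble and shControl libraries into groups of 4 and 3, only the real 1 gave as many called genes. It gave 3413 and the highest other split gave 1. Every other split mixed libraries of Map3k7 clones with controls. The splits cannot exclude chance, because they take libraries as independent and the 4 shDouble libraries come from 2 clones. Splits of 2 clones and 3 control lines are too few. With counts summed per line 590 genes were called. The excess correlation between comparisons that share controls was tested against simulated unchanged groups only. For shMap3k7 and shDouble part of r may come from the shared control libraries and the shared clones; r was 0.805 without shMap3k7 replicate 1. For the other pairs the negative r may come in part from clone 4, which both shChd1 and shControl hold and the simulations left out; without shControl replicate 2, r was -0.124 and -0.113.

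In 52 groups of 4 values a library was tested for standing apart, and chance gives such a library in about 1 in 20 groups. For Akr1c18, 1 shDouble library (replicate 2) stood apart in log2 CPM, at near 0 counts. For Col5a2, 1 shDouble library (replicate 2) stood apart in the same way.

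By camera with the preset correlation, 7 lists differed in the change with Chd1 hairpins between the Map3k7 clones and the comparison with the controls. None did with an estimated correlation. This difference also holds that of shControl replicate 2, the line of both shChd1 libraries, from the other controls. Against the control mean, shControl replicate 2 alone had a median of -0.63 for epithelial and 0.62 for interferon genes. Medians are given below, then those with the line as a replicate block, which rests on 1 control library for shChd1. The change with the hairpins was more positive in the Map3k7 clones for luminal markers (adjusted p = 0.0082; median 1.33, 0.44 with the block). It was more positive for basal markers, among them the laminin gene Lama3 (list adjusted p = 9.2e-07; median 0.94, 0.42 with the block). For epithelial junction and identity genes it was more positive (adjusted p = 7.8e-15; median 1.22, 0.48 with the block). The same held for JNK and AP-1 early response genes (adjusted p = 7.7e-07; median 0.72, 0.38 with the block). It was more negative for interferon response genes (adjusted p = 1.3e-11; median -1.1, -0.56 with the block). Cell cycle genes were shifted upwards (adjusted p = 0.0016; median 0.16, 0.24 with the block). This call was lost without shControl replicate 2 (median 0.10) or shChd1 replicate 1 (0.06). Hypoxia and glycolysis genes were shifted downwards (adjusted p = 1.0e-05; median -0.49, -0.18 with the block). With the block every one of these medians was smaller in size, except that of cell cycle genes.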

How the results depend on the processing

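Results below are given for each alternative that moved them; the fit with chromosomes centred was chosen only after the result was seen, and the cause of the shifts was not tested. The shMap3k7 against shControl count of 1712 was 805 with a fold threshold of 2, 2609 with the DESeq2 Wald test, 722 with limma-voom and a correlation within lines, 413 with counts summed per line and 193 with only the groups compared. The shChd1 against shControl count of 417 was 207 with the fold threshold, 684 with no low-count filter, 1715 with DESeq2, 142 with the line as replicate block, 0 with counts summed per line, 0 with only the groups compared and 729 with chromosomes centred. The shDouble against shControl count of 3413 was 1307 with the fold threshold, 1557 with the correlation within lines and 590 with counts summed per line. The shDouble against shChd1 count of 6426 was 2861, 3193 and 1674 under these settings. The interaction count of 0 was 31 with no low-count filter, 395 with DESeq2 and 11 with the line as replicate block. The count for clone 1 against clone 7 (4663) was 3012 with DESeq2 and 570 with the fold threshold. The count for construct 96526 against 96528 (5) was 0 with no replicate block, 417 with no low-count filter, 42 with DESeq2, 10 with limma-voom and 1 with the fold threshold.

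With each library left out in turn, counts ran from 261 to 2062 for shMap3k7 against shControl, 0 to 2641 for shChd1 against shControl, 2181 to 3286 for shDouble against shControl, 0 to 0 for shDouble against shMap3k7, 3683 to 6610 for shDouble against shChd1 and 0 to 1002 for the interaction. They ran from 2122 to 5913 for clone 1 against clone 7 and from 2 to 555 for the constructs. A group left with 1 library was assumed to vary like the others. The r of shMap3k7 and shChd1 ran from -0.260 to -0.124 and the genes called in the same direction from 0 to 70; for shMap3k7 and shDouble from 0.805 to 0.934 and from 253 to 1997; for shChd1 and shDouble from -0.266 to -0.113 and from 0 to 121.

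Reversed signs concerned values that were not called, except for Mtap in shDouble against shChd1, which was -1.67 with limma-voom and a correlation within lines. Map3k7 in shChd1 against shControl was -0.020 with chromosomes centred and ran from -0.0085 to 0.081 over left-out libraries. In shDouble against shMap3k7, Map3k7 ran from -0.067 to 0.035. In the interaction, Map3k7 was 0.019 with chromosomes centred. Of named-gene values 6257 stayed, 1012 lost their call, 96 gained one and 6 changed sign, and of list calls 938 stayed, 67 were lost and 0 changed sign.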

Other observations

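Map3k7 clones 1 and 7, each with its Chd1-hairpin derivatives, differed in many genes; this comparison and that of the hairpin constructs were planned, and the chromosome values below were described only after the result was seen. Robo1, an axon guidance receptor, was higher in clone 1 by 6.84 ± 0.48 on the log2 scale (9.74 ± 4.85 against 0.0922 ± 0.112 CPM; adjusted p = 1.5e-04, edgeR), and Gria3, a glutamate receptor subunit, by 6.44 ± 0.26. Il1a, an inflammatory cytokine, was lower in clone 1 by a log2 value of -4.69 ± 0.25 (1.27 ± 1.02 against 31.7 ± 22.8 CPM), the mucin glycosyltransferase gene Gcnt3 by -4.52 ± 0.25 and Fbn1, a microfibril component, by -4.44 ± 0.23. Of 13030 tested genes 4663 differed, 2590 higher and 2073 lower in clone 1. Chromosome 4 stood higher in clone 1 (0.34) than in clone 7 (0.13), chromosome 7 was lower in clone 7 (-0.34) and chromosome 8 higher there (0.27).

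Constructs 96526 and 96528, compared with the line as replicate block over 6 libraries, differed in 5 of 13175 genes, all higher with 96526. They included Ccng1, a p53 target that encodes cyclin G1 (261 ± 43.0 against 156 ± 22.1 CPM; log2 0.74 ± 0.06, adjusted p = 0.0068, edgeR) and Lrrfip1, a nucleic acid-binding repressor (log2 0.77 ± 0.06, adjusted p = 0.0068). At an unadjusted p under 0.05 there were 1219 genes.

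Splits into other groups of the same sizes were counted for both. For clone 1 against clone 7, 1 of the 10 splits of the 6 libraries, the real 1, gave as many genes (4663; highest other 2), and for the constructs 1 of 10 did (5; highest other 4). With 10 splits the share cannot fall under 0.05, so the splits are too few.

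Some transcripts varied widely among the controls. Krt6a stood at 576 ± 800 CPM in shControl, 140 ± 2.72 in shMap3k7, 6.52 ± 6.18 in shChd1 and 149 ± 43.2 in shDouble. Foxj1 stood at 122 ± 89.9, 256 ± 1.39, 7.46 ± 7.15 and 249 ± 19 CPM in the same order. The median of 5 endothelial markers against the control mean was 0.88, -0.55 and -0.81 in shControl replicates 1, 2 and 3. That of 8 fibroblast markers was 0.86, 0.32 and -0.96. Replicate 1 is the unnumbered control line at passage 30, labelled puro and neo where the others are labelled GFP and puro.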
